A study of Rattus norvegicus with 8 samples.

How the data were processed

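Gene expression was measured in the medial thalamus of conscious male Sprague-Dawley rats, 4 that had received tracheal occlusions and 4 surgical controls. Per the labels, sessions ran daily for 10 days, each occlusion covered 3 to 10 breaths with about 30 s of recovery, and the animals were killed within 10 min of the last session. Total RNA (1 µg per array) was labelled with Cy3 and hybridised to Agilent whole-rat oligonucleotide arrays, 1 array per animal. The group and the replicate number of each array came from the sample labels. The design text speaks of 4 animals per group, so replicates were taken as separate animals. It also mentions a reference design, but per the file headers each array was scanned in 1 channel, so the arrays were analysed as 1-colour arrays.

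Per the file headers, the authors used Agilent Feature Extraction 9.5.1.1, which wrote for every spot a raw intensity, a local background and a processed intensity that is background-subtracted, detrended and, for dim spots, replaced by a surrogate value. The processed intensity is linear and is not normalised between arrays. The deposited table of all 8 arrays holds the same processed intensity written with fewer digits, so neither its scale nor its direction is in doubt. Each array carried 45018 spots, of which 43379 were no controls and belonged to 41012 distinct probes. Flags per spot for being well above background, saturated or an outlier were used as deposited. No aligner or genome is involved, and probe positions are those of the file headers and columns (rat assembly rn3). No rn3 annotation was used, so the exon or untranslated region under a probe is not stated.

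For the main values, control spots and spots with an outlier flag were left out, the 75th percentile of log2 processed signal was subtracted on each array, and spots of one probe were averaged. Saturated spots were kept at their value. Probes were kept if well above background on at least 4 of the 8 arrays, counted without regard to group, and with at least 2 values in each group, which left 27152 probes. Of these, 1100 lacked a value on at least 1 array because of outlier flags. Probes were named through a table of rat genes (assembly GRCr8, used for names only). By accession 10735 probes were named, by another accession of the probe 117, by symbol 5537 and by synonym 3705, while 3309 kept the name in the files and 17609 had none. In all, 23403 probes carried 1 symbol, from 18332 distinct symbols. Contig accessions were at first read as symbols, and this was corrected after the first list of named genes had been seen. Where a gene had several probes, the probe with the highest mean signal over all arrays stood for it.

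Occlusion and control arrays were compared per probe with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all kept probes, threshold 0.05) in R 4.3.3. The 32 gene lists, 13 of them markers of cell types or neighbouring tissues, were tested with camera in limma at a preset correlation of 0.01 between genes, over 13007 genes with a value on every array. Beside it, camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run. Counts of members are over all kept members of a list, and were also adjusted over the list alone. Each array's mean over a marker list was compared with an exact permutation test (two-sided, 70 assignments, smallest possible p 0.0286). For a probe that was not well above background on any array of a group, a fold is given as a bound. It is the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

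Genes are named by a rule. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, with free places filled by the smallest p in that direction among genes whose groups do not overlap. It also takes, in each list, the 2 members with the highest and the 2 with the lowest moderated statistic, and the genes Htr2a, Htr1a, Drd1, Drd2, Fos, Egr1, Arc, Bdnf, Fkbp5, Sgk1, Nr3c1, Crh, Gfap, Mbp and Ttr in any case. Htr1a did not pass the filter on dim probes and has no value here. Some genes that the rule takes from the lists are not reported here. The tests between the groups, the gene lists, the rule for named genes and the alternative settings, except 3 that were added later, were fixed before the data were examined.

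Each group was spread over both slides, 2 arrays per group and slide, and each slide was scanned at its own time, so slide and scan are 1 batch. Alternatives were quantile normalisation, scaling to the median of kept probes, normexp background correction (offset 50) of the raw intensity, no filter on dim probes, a filter on all 8 arrays, a trended robust variance, array weights, the slide as a block, each slide alone, the replicate number as a block, the deposited table of all arrays, 1 value per gene, other thresholds, and each array left out in turn. A habenula marker mean as a covariate, a fit without the 3 arrays lowest in habenula markers and a fit without probes saturated on any array (in the list tests, without genes whose chosen probe was saturated) were added after seeing the data. The number of arrays limits the precision: the median SD within groups was 0.245 on the log2 scale and the median SE of a difference 0.171.

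The steps were tested on simulated data with the sample sizes and spreads of these arrays. With 200 of 27152 probes changed, the occlusion versus control fit recovered 26% of those changed 1.5-fold, 50% at 2-fold, 76% at 3-fold and 92% at 4-fold. It made 8 calls among unchanged probes there, and 0 calls when no probe was changed. In the simulated gene list test over 13007 genes, 1 list shifted by 0.5 was the 1 list called, and with no shift 0 lists were called. The simulated probes and genes varied independently of one another, while the real arrays share structure, such as that by slide, and members of the real lists move together. The simulation therefore does not show how many unchanged probes limma calls, or how many unshifted lists camera calls, on these arrays. Its recovery rates hold for independent probes. Figures were drawn with matplotlib 3.10.9.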

Results

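RNA from the medial thalamus of 8 rats was measured on 8 single-colour arrays, 4 from animals conditioned with tracheal occlusions (repeated brief blocks of the airway) and 4 from surgical controls that had none. The comparison asks which transcripts differ in the medial thalamus after 10 days of such conditioning. Between 65.0% and 71.6% of spots were well above background on each array, 1.05% to 1.55% were saturated, and the 75th percentile of processed signal lay between 1439 and 2216. No measure of array quality passed a test between the groups after adjustment, but 1 measure alone could not have passed it. The spike-in R² did not overlap between the groups (lowest occlusion array 0.98033, highest control array 0.98028). Its means were 0.985 on occlusion and 0.975 on control arrays (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.229 over 8 measures). Correlations between arrays ran from 0.953 to 0.986. The first principal component, with 37.7% of the variance, separated the 2 slides, each of which held 2 arrays of either group. Values below are log2 differences, occlusion minus control, with n = 4 and 4 unless another n is given. Counts of list members are over all measured members, while list means and camera use the members with a value on every array.

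On occlusion arrays Hcn4, a hyperpolarisation-activated pacemaker channel, was higher by 1.21 (SE 0.23, 2.31-fold), Kif1a, a motor for synaptic vesicle precursors, by 0.58 (SE 0.12), and Zfp365 by 0.99 (SE 0.22). Bche, the enzyme butyrylcholinesterase, was higher by 0.77 (SE 0.16). Lower were Htr2a, the serotonin 2A receptor, at -1.45 (SE 0.29, 2.73-fold), Sult1a1, a phenol sulfotransferase, at -1.06 (SE 0.17), and Emx2, a forebrain homeobox gene, at -2.77 (SE 0.52, 6.84-fold). None of these, and no other probe, passed the test: limma found 0 of 27152 probes at an adjusted p under 0.05, the smallest being 0.403, against 3010 probes at an unadjusted p under 0.05 (1759 higher, 1251 lower), where chance gives 1358. With the slide as a block the count was also 0 (smallest adjusted p 0.242) with 3868 probes at an unadjusted p under 0.05. Slide 1 alone gave 0 with 1701 and slide 2 alone 0 with 2688. Groups did not overlap for 1823 probes (6.71%), where chance gives 2.86%.

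By the rule for named genes, 12 genes per direction were taken from those with the smallest p whose groups did not overlap, and all 24 did not pass. The higher ones were LOC682080 (0.98), Or12j4 (1.28), RGD1562081 (0.94), Hcn4, Osbp2 (0.74), Or8i2 (0.79), Plekhm2 (0.52), Kif1a, Bche, Adgrb1 (0.76), Zfp365 and Scrt1 (0.81). Or12j4 and Or8i2 are olfactory receptor genes, Osbp2 encodes an oxysterol-binding protein, Adgrb1 an adhesion receptor and Scrt1 a neural transcriptional repressor. Of these, the probes of LOC682080, Or12j4 and Or8i2 were well above background on 1, 2 and 3 of the 4 control arrays. The lower ones were Bphl (-0.99), RGD1560658 (-1.86), Sult1a1, Emx2, Abcg3l4 (-0.54), Adgrg6 (-0.78), Rnf39 (-0.78), Spag1 (-0.72), LOC690211 (-0.79), Htr2a, Tmx1 (-0.62, 3 occlusion arrays) and Wsb1 (-0.76). Bphl encodes a hydrolase, Adgrg6 an adhesion receptor and Tmx1 a thioredoxin-related membrane protein. Their SEs ran from 0.10 for Abcg3l4 to 0.52 for Emx2. A second Kif1a probe read 0.03 (SE 0.20), and a second Adgrb1 probe 0.33 (SE 0.22).

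**Figure D1:**
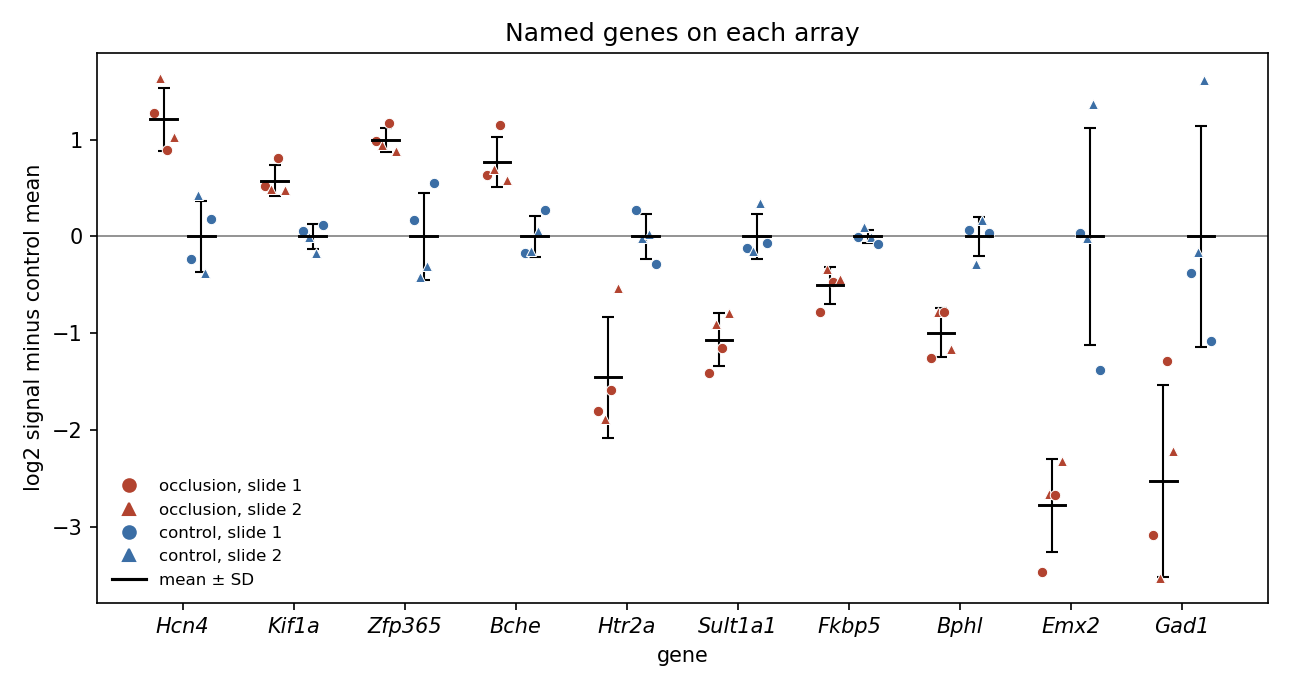
Log2 signal of 10 named genes on each array, relative to the mean of the 4 control arrays (vertical axis, log2 units). Points are single arrays, circles slide 1 and triangles slide 2, and black lines give the mean ± SD. All 4 occlusion arrays lie above the control arrays for Hcn4 and below them for Htr2a and Emx2, though no gene passed the adjusted test.

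The probe for Htr2a lies on chromosome 15 at 55549339 to 55549398 (rn3). Its level was -4.60 ± 0.62 (SD, n = 4) on occlusion and -3.15 ± 0.23 on control arrays, and the difference was -1.69 within slide 1 and -1.22 within slide 2. The Hcn4 probe, on chromosome 8 at 62686228 to 62686287, read -2.93 ± 0.33 (SD) and -4.14 ± 0.37, with 1.11 and 1.30 within the slides. The Sult1a1 probe, on chromosome 1 at 185979634 to 185979693, read -1.77 ± 0.28 (SD) and -0.70 ± 0.23, with -1.18 and -0.94 within the slides. The Emx2 probe, on chromosome 1 at 266222114 to 266222173, read -3.30 ± 0.48 (SD) and -0.53 ± 1.12, with -2.39 and -3.16. For Kif1a (chromosome 9, 92565818 to 92566561) the slides gave 0.58 and 0.57. Each of these had an adjusted p of 0.403 in limma, and of 0.242 with the slide as a block.

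Monoamine receptors, activity-induced genes and stress genes had been set in advance to be given as measured. Drd2, the dopamine D2 receptor, was lower at -0.80 (SE 0.24) and Fkbp5, a co-chaperone of the glucocorticoid receptor, at -0.50 (SE 0.12), the latter on 3 probes (-0.49, -0.62 and -0.50). Ttr, the transthyretin made by choroid plexus, was higher by 1.83 (SE 0.69), with 2.56 and 1.105 within slides 1 and 2. The activity-induced genes Fos (0.02, SE 0.43), Egr1 (-0.64, SE 0.49) and Arc (-1.13, SE 0.73), and the neurotrophin Bdnf (-0.16, SE 0.31), differed by less than 2 SEs. The same held for Drd1, the dopamine D1 receptor (-0.08, SE 0.35), Sgk1 (-0.30, SE 0.47), the glucocorticoid receptor Nr3c1 (0.15, SE 0.15), the stress peptide Crh (0.08, SE 1.24) and the astrocyte filament Gfap (-0.42, SE 0.32). Mbp, myelin basic protein, had 2 probes that disagreed in sign: the brighter, higher on occlusion arrays, was saturated on 2 of 3 occlusion and all 4 control arrays, so no difference is given for it, and the other read -0.56 (SE 0.22). A second Bdnf probe read 0.05 (SE 0.33). No adjusted p among these genes was under 0.403. Single arrays moved some of these values: without control 3 Arc read -0.30 (SE 0.21), Egr1 -0.31 (SE 0.46) and Bdnf -0.47 (SE 0.18), without control 1 Egr1 read -1.12 (SE 0.31), and without control 4 Arc read -1.52 (SE 0.75) and Gfap -0.73 (SE 0.22). Bdnf moved the other way, toward no difference, without control 1 or without control 4, and Nr3c1 shrank without occlusion 1. The sign of Drd1, Fos, Arc, Bdnf, Sgk1 and Crh was not the same within both slides (Drd1 -0.67 and 0.51, Fos 0.34 and -0.30, Arc 0.06 and -2.31, Bdnf -0.81 and 0.50, Sgk1 -0.91 and 0.32, Crh -0.58 and 0.73).

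Markers of thalamic relay neurons, the excitatory cells that project to cortex, were higher on occlusion arrays, and markers of the reticular thalamic nucleus, the inhibitory shell of the thalamus, were lower. All 14 measured relay markers were higher, with a list mean of 0.81, among them Ntng1 (1.29, SE 0.34), Lef1 (1.45, SE 0.50) and Lhx9 (0.51, SE 0.43), and 0 of the 14 passed over all genes or adjusted over the list alone. Of the 14, 3 were saturated on at least 1 array and 1 on every array, so their direction is uncertain. The 11 never saturated were all higher, with a mean of 0.90. Of 10 reticular markers 9 were lower, by a mean of -1.51 over the list, with Gad1, a GABA-synthesising enzyme, at -2.52 (SE 0.65, 5.75-fold) and Slc32a1, the vesicular GABA transporter, at -2.03 (SE 0.62). Gad1, Slc32a1 and Gad2, also lower, stand in the GABA list too, and Sst, also lower, in the neuropeptide list. The fall of these genes is not specific to the reticular nucleus. Of the 10 reticular markers, 0 passed over all genes and 1, Gad1, passed adjusted over the list alone (adjusted p = 0.0427). Without control 3 Lef1 read 0.94 (SE 0.29) and Lhx9 0.10 (SE 0.28). All 3 Gad1 probes were lower (-2.87, -2.90 and -2.52). The first 2 were well above background on 2 and 1 of 4 occlusion arrays, so their sizes are uncertain. By camera the relay list rose (adjusted p = 1.7e-05) and the reticular list fell (adjusted p = 0.00118), and with the slide as a block both calls stood (2.3e-05 and 0.00205). With an estimated correlation neither did (adjusted p = 0.626 for both). Within slide 1 the shifts were 0.44 and -0.61, and within slide 2 1.18 and -2.42.

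The array means gave the same directions with less certainty. The relay list read 0.96 ± 0.21 (SD, n = 4) on occlusion and 0.15 ± 0.47 on control arrays, with no overlap (exact permutation p = 0.0286, the smallest possible). The reticular list read -2.27 ± 0.80 and -0.76 ± 0.79 (exact permutation p = 0.0571). After adjustment over the 13 marker lists 0 lists passed by this test (adjusted p = 0.371 for both). With a smallest possible p of 0.0286, a list could pass only if many of the 13 reached it, so the adjusted result says little. Camera called 4 of the marker lists.

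**Figure D2:**
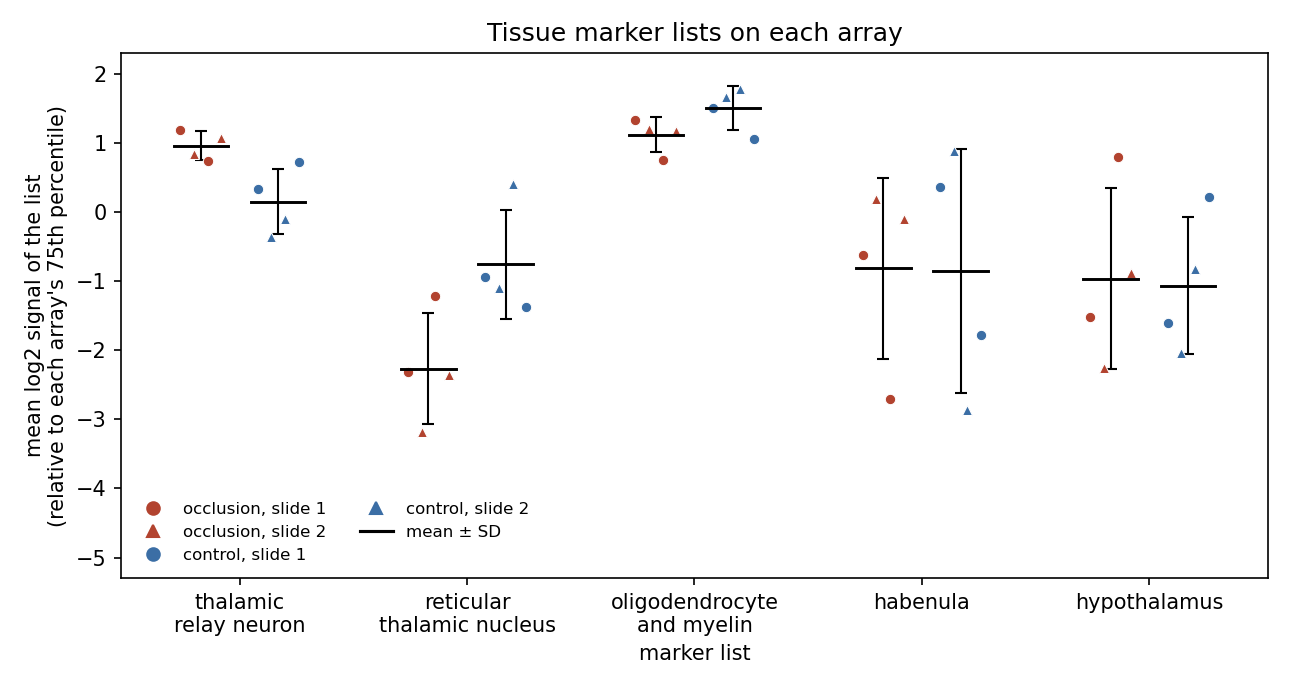
Mean log2 signal of 5 tissue marker lists on each of the 8 arrays, relative to the array's 75th percentile (vertical axis). Circles are slide 1, triangles slide 2, and black lines the mean ± SD of 4 arrays. Relay markers on occlusion arrays (lowest 0.73) lie above those on control arrays (highest 0.72), while habenula markers span 3.74 log2 units over arrays of both groups.

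Genes of neuronal excitability and of transmitter release were also higher as groups. Of 21 pacemaker and low-threshold channel genes 16 were higher, with a list mean of 0.28, led by Hcn4 and by Kcnj9, an inwardly rectifying potassium channel (1.24, SE 0.35). Of 26 synaptic vesicle and presynaptic genes 21 were higher, with a mean of 0.24 over 25 members, among them Syn1 (0.53, SE 0.15) and the calcium sensor Syt1 (0.47, SE 0.14, other probes 0.23 and 0.60), against Cplx2, a complexin, at -1.003 (SE 0.37) and Vamp1 (-0.43, SE 0.32, and -0.22 without control 2, -0.27 without control 1 and -0.69 without control 3). Of the 26, 5 were saturated on at least 1 array and 2 on every array, and the 21 never saturated divided into 16 higher and 5 lower. Of 29 glutamate receptor and transporter genes 20 were higher, with a mean of 0.19 over 27 members, among them the metabotropic receptors Grm4 (1.18, SE 0.34) and Grm2 (0.89, SE 0.26), against Grm8 (-0.73, SE 0.28) and Grik2 (-0.34, SE 0.14). No member of these 3 lists passed over all genes, and adjusted over the list alone 1 did, Hcn4 (adjusted p = 0.0126). By camera all 3 rose, with adjusted p of 0.0117, 0.000187 and 0.033, and with the slide as a block 0.0264, 0.000147 and 0.0402. With an estimated correlation the adjusted p was 0.626 for each. Within slide 1 the shifts were 0.13, 0.15 and 0.08, and within slide 2 0.42, 0.34 and 0.30, and the array means of the 3 lists correlated with those of the relay markers at r = 0.924, 0.736 and 0.856 over the 8 arrays and at r = 0.831, 0.448 and 0.729 after removal of the group means, though the relay markers share Cacna1g with the first list and members such as Slc17a6 with the third. Without control 3 the synaptic vesicle mean was 0.15 (adjusted p = 0.00221). The glutamate call was lost without occlusion 2 (adjusted p = 0.0857), occlusion 4 (0.113), control 1 (0.0518) or control 2 (0.0565), with scaling to the median (0.0513), with the filter on all 8 arrays (0.0855) and without the 3 members saturated on any array (0.088, a fit chosen after seeing the data).

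Myelin and choroid plexus genes were lower as groups. Of 19 oligodendrocyte and myelin markers 17 were lower, with a mean of -0.38 over 16 members, among them the myelin proteins Mal (-1.01, SE 0.35) and Mobp (-0.71, SE 0.26, 2 occlusion arrays, saturated on 1 control array; other probes -0.43 and -0.29). The 4 members saturated on any array include Mbp, and all 15 others were lower. Of 12 choroid plexus and ependymal markers 9 were lower, with a mean of -0.16 and a median of -0.42, among them the chloride channel gene Clic6 (-0.91, SE 0.26) and Kcne2 (-0.75, SE 0.26), against Ttr. In both lists 0 members passed over all genes or adjusted over the list alone. Camera called both lower (adjusted p = 0.000409 and 0.033; 0.000158 and 0.0317 with the slide as a block), and with an estimated correlation the adjusted p was 0.726 and 0.849. Within slides 1 and 2 the myelin list read -0.23 and -0.53, and the choroid plexus list 0.06 and -0.39. Over the 8 arrays the means of the myelin and choroid plexus lists correlated with those of the relay markers at r = -0.693 and -0.593. After removal of the group means r was -0.433 and -0.729. By the exact permutation test neither list's array mean passed (p = 0.114 and p = 0.686). The choroid plexus call was lost without occlusion 1 (0.065), occlusion 3 (0.078), occlusion 4 (0.0813), control 1 (0.123), control 2 (0.0943) or control 3 (0.14), with no filter on dim probes (0.0995), with the filter on all 8 arrays (0.0709) and when probes saturated on any array, none of them in this list, were left out of all lists (0.0521). Its mean was -0.09 without occlusion 1, 0.0015 without control 1, -0.06 without control 2 and -0.48 without control 4 (adjusted p = 0.000289).

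Among metabolic and regulatory groups, 23 of 24 cholesterol synthesis genes were higher, with a mean of 0.24 over 21 members, among them the regulator Srebf2 (0.43, SE 0.20, 0.25 without occlusion 3, and 0.11, SE 0.23, on a second probe) and Mvd (0.44, SE 0.24, and 0.20 without control 3). Of 16 circadian clock genes 12 were higher, with a mean of 0.27 over 15 members, among them the nuclear receptor Rorb (0.70, SE 0.16) and the transcription factor Hlf (1.26, SE 0.40, well above background on 2 of 4 control arrays), against Per3 (-0.31, SE 0.10). The array means of the clock list followed those of the relay markers at r = 0.988 over the 8 arrays, with no shared member, and at r = 0.992 after removal of the group means. Of 62 oxidative phosphorylation genes 54 were higher, with a mean of 0.10 over the 47 members with a value on every array, but 33 of the 62 were saturated on at least 1 array and 23 on every array, where the signal is only a lower bound. Of the 29 never saturated 22 were higher, among them Atp5f1d at 0.37 (SE 0.13). Of 73 cytosolic ribosomal protein genes 61 were higher, with a mean of 0.11 over the 49 members with a value on every array, but 47 were saturated on at least 1 array and 36 on every array. Of the 26 never saturated 15 were higher and 11 lower, among the latter Rpl4 at -0.32 (SE 0.11, 3 occlusion arrays). Of 27 glucocorticoid-responsive genes 19 were lower, with a mean of -0.20 over 25 members, among them Sult1a1 and Fkbp5, against the small GTPase Rhob (0.58, SE 0.24) and the phosphatase Dusp1 (0.57, SE 0.33, and 0.34 without control 1). No member of these 5 lists passed over all genes. Adjusted over the list alone Sult1a1 (adjusted p = 0.00679), Fkbp5 (0.0385) and Rorb (0.0418) did.

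Camera called each of these 5 lists, but without probes saturated on any array, a fit chosen after seeing the data, oxidative phosphorylation (mean 0.08 over 24 members, adjusted p = 0.124) and ribosomal proteins (0.07 over 19, adjusted p = 0.377) did not pass. That fit also cut the members tested from 47 to 24 and from 49 to 19. A saturated probe sits at a ceiling, so its scaled value follows the array's 75th percentile. That percentile averaged 1713 on occlusion and 1876 on control arrays, so scaling alone puts saturated members higher on occlusion arrays on average. Quantile normalisation, which kept these members, also ended both calls (values below). These results argue that saturation carried part of both calls, while the share of the smaller lists cannot be told. With all members the adjusted p was 0.00483 for cholesterol synthesis, 0.0131 for the clock genes, 0.0117 for oxidative phosphorylation, 0.0117 for ribosomal proteins and 0.0131 for the glucocorticoid-responsive genes. With the slide as a block it was 0.00806, 0.0219, 0.0255, 0.0219 and 0.0159. With an estimated correlation the adjusted p was 0.849 for the cholesterol, oxidative phosphorylation and ribosomal lists and 0.726 for the clock and glucocorticoid-responsive lists. Within slides 1 and 2 the cholesterol list read 0.04 and 0.43, the clock list 0.10 and 0.44, oxidative phosphorylation 0.16 and 0.05, ribosomal proteins 0.24 and -0.03, and the glucocorticoid-responsive list -0.33 and -0.07. Single arrays ended some calls: cholesterol without control 3 (0.297), clock genes without occlusion 4 (0.15) or control 2 (0.0565), oxidative phosphorylation without occlusion 2 (0.131), control 3 (0.228) or control 4 (0.0604), ribosomal proteins without occlusion 2 (0.0943), occlusion 3 (0.29) or control 4 (0.106), and the glucocorticoid-responsive list without occlusion 3 (0.251) or control 3 (0.106). The means without these arrays were 0.08 for cholesterol (control 3), 0.05 for oxidative phosphorylation (control 3), 0.04 for ribosomal proteins (occlusion 3), and -0.10 and -0.13 for the glucocorticoid-responsive list (occlusion 3 and control 3). Without occlusion 4 oxidative phosphorylation read 0.18 and ribosomal proteins 0.21, and both calls stood. Occlusion 4 had the highest 75th percentile (2216), so saturated members lay lowest there after scaling. Leaving it out raises them on the occlusion side, so this fit adds no support for the 2 calls. Quantile normalisation ended the calls of oxidative phosphorylation (0.371) and ribosomal proteins (0.933), and no filter on dim probes that of the glucocorticoid-responsive list (0.0549). Without the 3 arrays lowest in habenula markers (occlusion 3, control 3 and control 4), a fit chosen after seeing the data, the cholesterol (0.301), oxidative phosphorylation (0.819), ribosomal (0.97) and glucocorticoid-responsive calls (0.943) were lost.

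In all, camera called 12 of the 32 lists, 8 higher and 4 lower, and without probes saturated on any array 8 of these, 5 higher and 3 lower. With an estimated correlation 0 were called (smallest adjusted p 0.626, and 0 lists at an unadjusted p under 0.05), and with fry 0 were called (smallest adjusted p 0.274, with 5 lists at an unadjusted p under 0.05). Among the 12 called lists the estimated correlation ran from 0.041 (glutamate) to 0.643 (ribosomal proteins). All lie above the preset 0.01, and a preset that is too low makes camera's p too small.

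**Figure D3:**
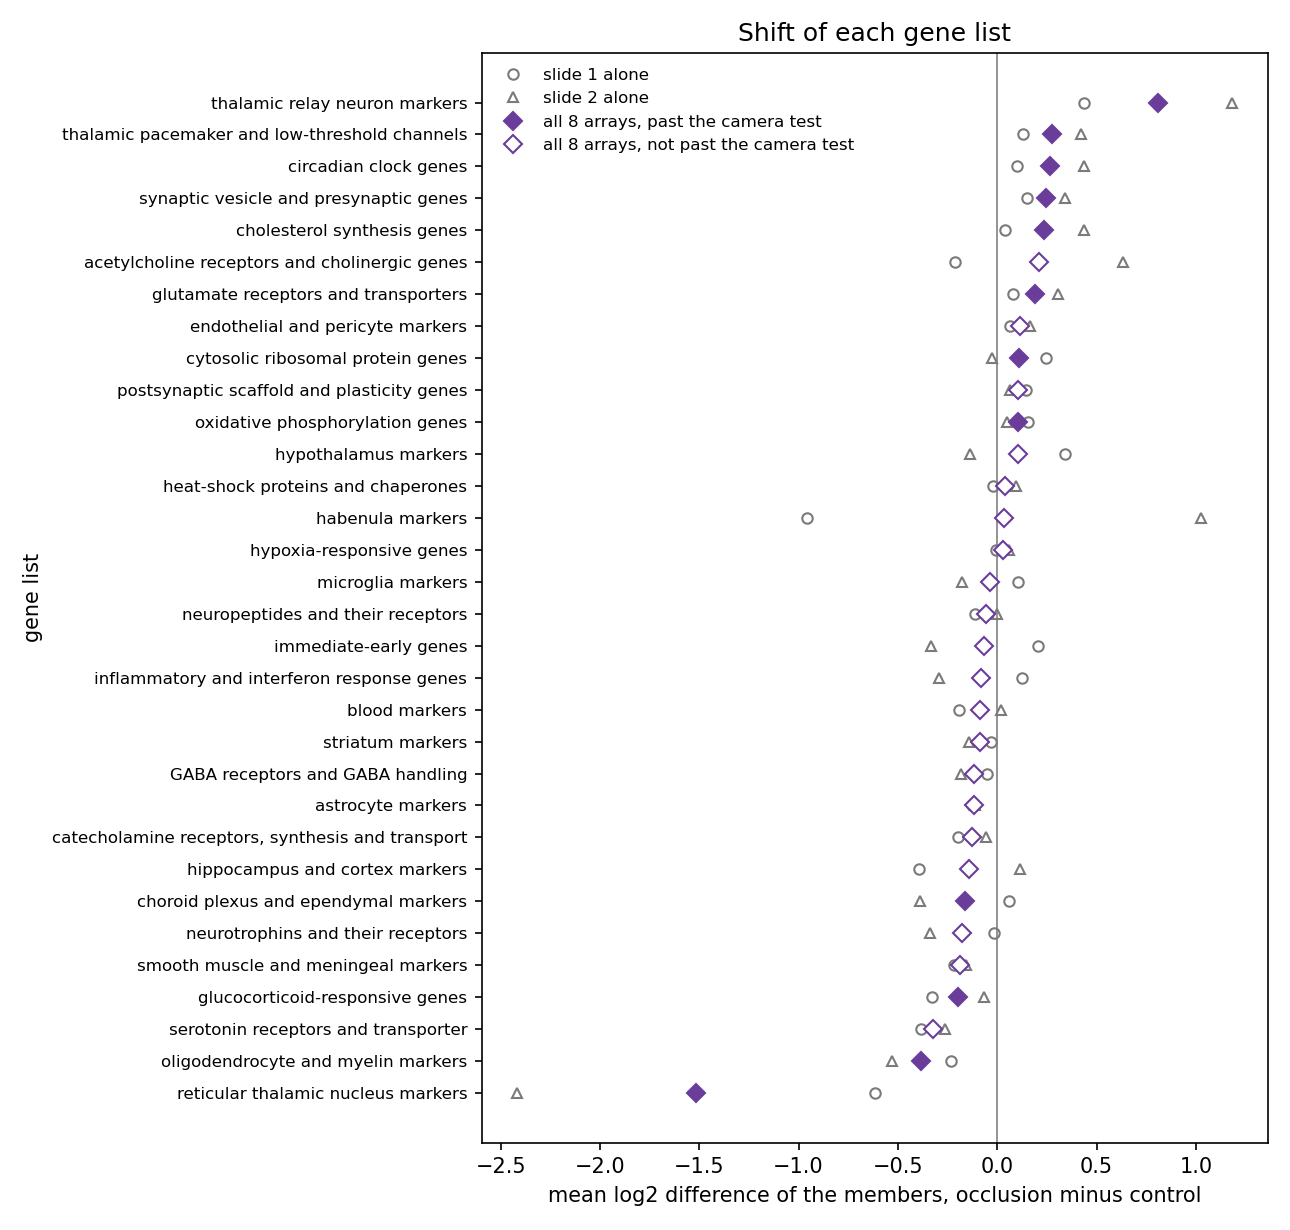
Mean log2 difference of the members of each of 32 gene lists, occlusion minus control (horizontal axis). Filled diamonds mark the 12 lists past the camera test, open diamonds the others, and grey circles and triangles the same mean within slide 1 and slide 2 alone. Relay neuron markers lie farthest to the right (0.81) and reticular nucleus markers farthest to the left (-1.51).

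The other transmitter lists did not pass. Of 11 serotonin receptor and transporter genes 9 were lower (adjusted p = 0.2; -0.38 and -0.26 within slides 1 and 2), with Htr2a passing adjusted over the list alone (adjusted p = 0.0114), Htr1d at -0.90 (SE 0.34, well above background on 1 of 4 occlusion arrays), and Htr1b at 0.56 (SE 0.22, 1 of 4 control arrays, 0.36 without control 2), while Htr7 read 0.46 (SE 0.24, 0.28 without control 2) on 1 probe and -0.02 (SE 0.24) on another. Of 19 catecholamine genes 10 were lower (adjusted p = 0.399), with the adrenergic receptors Adra2c at -0.86 (SE 0.26) and Adra1b at 1.30 (SE 0.56, 3 occlusion arrays). Of 21 GABA genes 11 were higher (adjusted p = 0.983), among them the receptor subunits Gabrd (1.59, SE 0.51) and Gabra4 (0.97, SE 0.36), against Gad1 and Slc32a1, which the reticular list also holds. Of 14 cholinergic genes 10 were higher (adjusted p = 0.166; -0.21 and 0.63 within slides 1 and 2), with the nicotinic subunits Chrna4 (0.97, SE 0.33) and Chrnb2 (0.68, SE 0.20), against the muscarinic receptor Chrm4 (-0.84, SE 0.40, and -0.43 without control 3). Of 45 neuropeptide genes 27 were lower (adjusted p = 0.353), with Avpr1a (-1.02, SE 0.34) and Pnoc (-1.05, SE 0.38, 3 control arrays), against Npy1r (1.11, SE 0.36) and Cck, for which no difference is given because it was saturated on 3 occlusion arrays and 1 control array. Of 14 neurotrophin genes 8 were lower (adjusted p = 0.773), with Ngfr at -1.50 (SE 0.66) and Cntfr at 0.62 (SE 0.26), which read -0.75 (SE 0.17) and 0.39 (SE 0.20) without control 3. Of 29 postsynaptic genes 17 were higher (adjusted p = 0.353), and adjusted over the list alone 6 passed, 5 higher and 1 lower, among them Dlgap3 (1.03, SE 0.24) and Dlg1 (-0.64, SE 0.17). In the other lists of this group 0 members passed adjusted over the list alone. Single arrays brought calls: the serotonin list passed without occlusion 1 (adjusted p = 0.0401), the cholinergic (0.0447) and neuropeptide lists (0.0214) without occlusion 3, and the postsynaptic list without control 3 (0.0219) and without the 3 arrays lowest in habenula markers (0.0101).

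The immediate-early, hypoxia-responsive, chaperone and inflammatory lists did not pass camera. The 36 immediate-early genes divided into 18 higher and 18 lower (adjusted p = 0.924), with the phosphatase Dusp6 at 0.54 (SE 0.19), Klf10 at -0.56 (SE 0.17, a second probe -0.23) and Ptgs2 at -0.78 (SE 0.33), and the list read 0.20 within slide 1 and -0.33 within slide 2. The 24 hypoxia-responsive genes divided into 12 and 12 (adjusted p = 0.773), with Bnip3 at 0.26 (SE 0.13) and Egln3 at -0.59 (SE 0.25). Of 21 chaperone genes 13 were higher (adjusted p = 0.686), with Hsph1 at 0.46 (SE 0.21, 0.30 without control 3) and Bag3 at -0.49 (SE 0.20, 3 occlusion arrays). Of 25 inflammatory and interferon genes 16 were lower (adjusted p = 0.353), with Gbp2 at -0.37 (SE 0.20, -0.25 without control 3) and Ifit2 at 0.58 (SE 0.29, 0.35 without occlusion 1), and without occlusion 1 the list passed with a mean of -0.22 (adjusted p = 0.0037). In these 4 lists 0 members passed over all genes or adjusted over the list alone.

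Markers of other cells and of tissues next to the dissected block did not pass camera (adjusted p from 0.166 to 0.983) or the exact permutation test. Of 17 astrocyte markers 9 were higher and 8 lower, with Aqp4 at -0.87 (SE 0.27) and Vim at -0.63 (SE 0.22), and the array mean differed by -0.12 (SE 0.09), or by -0.07 without occlusion 1 and -0.18 without control 4. Of 18 endothelial and pericyte markers 14 were higher, with Abcc9 at 0.60 (SE 0.20), and the mean differed by 0.12 (SE 0.08), or by 0.06 without control 3. Members higher and lower numbered 8 and 8 for microglia, 2 and 13 for smooth muscle and meninges, 2 and 6 for blood, 4 and 9 for striatum, 6 and 8 for hypothalamus, 5 and 7 for habenula, and 7 and 4 for hippocampus and cortex. The means of microglia (-0.04, SE 0.10), smooth muscle and meningeal (-0.19, SE 0.23), blood (-0.09, SE 0.47), striatum (-0.09, SE 0.11), hypothalamus (0.10, SE 0.82), habenula (0.04, SE 1.099) and hippocampus and cortex markers (-0.14, SE 0.25) each differed by less than 1 SE, with Pde1b of the striatum list at 0.47 (SE 0.21). The habenula mean was -0.96 within slide 1 and 1.03 within slide 2, and its sign turned with normexp background correction (-0.11). Camera called smooth muscle and meningeal markers without occlusion 2 (mean -0.31, adjusted p = 0.0226) or control 4 (-0.34, adjusted p = 0.016), and habenula markers without the 3 arrays lowest in them (-0.80, adjusted p = 0.000112). The habenula call is no evidence of a difference, since the arrays left out (occlusion 3, control 3 and control 4) were chosen by the same markers. No member of these lists passed over all genes, and adjusted over the list alone 2 did, in opposite directions and both in the hippocampus and cortex list, Emx2 (adjusted p = 0.00721) and Prox1 (0.0235). Prox1 was not well above background on any control array and was at least 2.22-fold higher on occlusion arrays. The mean, the median and the camera test did not share a sign for the immediate-early (mean -0.07, median 0.01), GABA (-0.12 and 0.18), habenula (0.04 and -0.09), hypothalamus (0.10 and -0.01) and hippocampus and cortex lists (-0.14 and 0.13).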

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

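The tests of array response, slide, scaling and habenula tissue below were chosen only after the results they bear on had been seen.

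Relay markers were higher and reticular markers lower on the occlusion arrays, a gap of 2.32 between the list means (exact permutation p = 0.0571). Each slide held 2 arrays of either group, so a constant offset between the slides cannot produce this gap. Slide 1 had the smaller relay difference, 0.437 (SE 0.30). Its reticular difference was -0.614 (SE 0.592), too close to its SE to decide anything within that slide. Scaling is argued against, since the smaller relay difference under quantile normalisation and normexp was 0.68. A different tissue make-up of the dissected block may account for the pattern: across 12402 genes outside the lists, the slope on the relay minus reticular score within groups correlated with the difference between groups at r = 0.438. That test separates poorly, because 5 of the 35 splits of the arrays gave as large a value (highest other 0.49), r ran from 0.132 to 0.509 with single arrays left out, and genes are not independent replicates. Tissue make-up and an effect of the occlusions both stay open, the latter untested.

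More probes than chance gives lay at an unadjusted p under 0.05, 3010 in all, while 0 passed the adjusted test and 12 gene lists passed camera. Of the 35 splits of the 8 arrays into 4 and 4, 3 gave at least 3010 (highest other 3640) and 5 gave at least 12 lists (highest other 15), so chance cannot be excluded for either count, while the 0 adjusted calls cannot be tested in this way, since each of the 35 splits reaches 0 by construction (highest other 1826). The split by slide gave the 1826 adjusted calls and 3636 at an unadjusted p under 0.05, which points to a structure of the arrays by slide, and with the slide as a block the real counts were 0 and 3868. Among the 18 splits balanced over the slides, the real one had the most probes (highest other 2279), but 4 gave at least 12 lists. Mean spike-in slopes were 0.978 on occlusion and 1.04 on control arrays (exact permutation p = 0.114, adjusted p = 0.457 over 8 measures). Control 1, at 0.962, lay among the occlusion arrays (0.957 to 0.994). An uneven response of the arrays is argued against as the whole cause by 3007 probes at an unadjusted p under 0.05 after quantile normalisation. Of these, 2594 were among the 3010, and an effect of the occlusions stays open.

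Habenula markers ranged over 3.74 log2 units between arrays of both groups. Array signal quality is argued against, since the widest of 10000 random lists matched in size and signal ranged over 1.66. Members moved together, with a mean correlation of 0.816 between 11 members after removal of group means (lowest 0.455). A list mean with so wide a range calls for members that move together. That correlation therefore cannot tell habenula tissue from another shared cause. Different amounts of habenula in the dissected block are a candidate explanation. Of the 12 measured markers, 5 also stand in the cholinergic list, and medial thalamus borders the habenula. No biological explanation was tested, because both groups hold high and low arrays.

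In 20 of 267 groups of 4 values, 1 array stood far from the other 3, where chance gives about 13; control 3 did so in 4 and control 4 in 4. The spike-in slope of control 1 was 0.962 against at least 1.05 on the other control arrays. Among list means, control 4 was high for neuropeptides (-0.29) and control 2 low for GABA genes (-0.10). Occlusion 3 was high for catecholamine genes (-1.88), occlusion 1 for pacemaker channels (-0.77) and occlusion 2 for hippocampus and cortex markers (-2.04), while occlusion 4 was low for oxidative phosphorylation (4.03), where 23 of 62 members were saturated on every array and the ceiling after scaling is lowest on occlusion 4, the array with the highest 75th percentile (2216). Among genes, control 3 was high for Ngfr (-0.37), Avpr1a (-2.09) and Sult1a1 (-0.36) and low for Atp5f1d (3.83). Control 4 was high for Crh (-0.60) and low for Gfap (-0.21) and Aqp4 (-1.07), and control 2 was low for Or8i2 (-5.36). Occlusion 3 was high for Kif1a (3.79) and Drd2 (-3.42), occlusion 2 high for RGD1562081 (-3.36), occlusion 1 low for Abcg3l4 (-2.44) and occlusion 4 low for Cck (4.82), which was saturated on 3 occlusion arrays, so that this gap follows the same ceiling.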

How the results depend on the processing

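The covariate of habenula markers, the fit without the 3 arrays lowest in them (occlusion 3, control 3, control 4) and the fit without saturated probes were chosen after seeing the data. In 23 other settings of limma, with 1 value per gene and at the other adjusted thresholds, 0 probes passed except with normexp. There 1 did (adjusted p = 0.0478, range over settings 0.0478 to 0.72), the unnamed probe A_44_P114424, singled out after its values were seen and higher by 1.42 (SE 0.16) in the main values. At an unadjusted p under 0.05 the count of 3010 moved by over 1.5 times only in slide 1 alone (1701, with fewer arrays), and with 1 array left out it ran from 2042 to 3967. Of 97 named genes, 88 never turned sign, and 0 passed in any. The others turned sign as follows, and the cause was not tested. In slide 1 alone Arc read 0.0555, Crh -0.58, Lhx9 -0.12, Hsph1 -0.0036 and Gbp2 0.0375, and in slide 2 alone Drd1 0.51, Fos -0.30, Bdnf 0.50 and Sgk1 0.32. With array weights Sgk1 read 0.0112 and Crh -0.24. Without the 3 arrays low in habenula markers Drd1 read 0.13, Sgk1 0.71 and Crh -0.16, the ribosomal list turned sign with a mean of -0.0036, and for the glucocorticoid-responsive list camera's direction turned while the mean, -0.0022, kept its sign. With 1 array left out Drd1 ran from -0.35 to 0.24, Fos from -0.40 to 0.22, Sgk1 from -0.59 to 0.0158, Crh from -0.98 to 1.02 and the choroid plexus list from -0.48 to 0.0015, the last without control 1. Of the 32 gene lists, 0 passed with an estimated correlation and 0 with fry, 12 with the slide as a block, 10 with quantile normalisation, 11 with the median and 9 to 13 with 1 array left out, of which 8 to 11 were among the 12. The habenula covariate gave 12, and the fit without the 3 arrays 10, of which 8 were among the 12. Without probes saturated on any array 8 of the 12 passed, with 0 probes past the adjusted test and 2976 at an unadjusted p under 0.05, and Cck, Mbp and Mobp had no value. With the replicate block limma gave 0 probes (2834 at an unadjusted p under 0.05) and camera 12 lists. The marker lists gave 0 by exact permutation within numbers, where the smallest possible p of 0.125 allows no call. Whether the numbers pair the arrays cannot be told. Same-numbered arrays correlated in their deviations at 0.355, 0.514, -0.0715 and -0.293, and 4 of 8 arrays correlated best with their own number. The 2 arrays of number 1 share a slide, as do those of number 2, while those of numbers 3 and 4 do not. Between arrays of different groups the mean such correlation was 0.285 on the same slide and -0.286 on different slides, so slide and number are mixed here. Signal over background limits dim genes, such as Htr1a, which was left out, and Drd1, well above background on 3 of 4 arrays in each group.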

Other observations

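The genes named here and the test of the hypothalamus list were chosen only after the results were seen.

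Genes of tissues next to the medial thalamus differed widely between animals of the same group. Gpr151, a receptor of habenular neurons, read between -6.32 and 1.31, and Chrna3, a nicotinic subunit abundant there, between -5.85 and 1.88, both lowest on control 3 and highest on control 2. Hypothalamic peptide genes peaked on other arrays. Oxt, oxytocin, read 5.51 on occlusion 3 and 5.06 on control 4, and Avp, vasopressin, 5.44 and 5.06 on the same arrays, against -5.59 and -1.84 on occlusion 2. Pmch, melanin-concentrating hormone, was high on occlusion 4 (4.68) and control 4 (5.02), and Pomc, the opiate peptide precursor, on occlusion 4 (4.88), where no other array passed 1.08. Each of these 4 genes was saturated on at least 1 array, so their highest values are lower bounds. Over the 8 arrays the hypothalamus list ranged over at least 3.06 log2 units, while the widest of 10000 random lists of its size ranged over 1.8.

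Between the slides, 1826 probes passed limma, but among the gene lists 1 did by camera: oligodendrocyte and myelin markers, higher by 0.29 on slide 2 (adjusted p = 0.00182). Control 3 correlated least with the other arrays, at a mean r of 0.964 against 0.977 for all other pairs.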
